A study of Mus musculus with 26 samples.

How the data were processed

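Thalamic neurons of mice that carried a retrograde label from 1 of 5 cortical systems (auditory, motor, prefrontal, somatosensory or visual) were taken from brain slices and sorted by hand, per the labels' protocols. The slices had been kept in blockers of neuronal activity during preparation, per the labels' protocols. Single cells were made into 3' libraries with UMIs and spike-in RNAs on 26 plates, which are the deposited samples. Reads were processed with cutadapt 1.16, Picard 1.12 and STAR 2.5.3 on build mm10, per the submitters' processing notes. The gene annotation behind the table and the rule for counting were not given in the sources used here, so antisense or overlapping genes and genes with near-identical copies may share UMIs. The authors deposited counts, which are raw UMI counts per gene and cell with no normalization, and a cell table with plate, animal, sort date, system, batch and cluster. The sum over genes equalled the deposited total in 1972 of 1972 cells. Of the gene columns, 1425 were at 0 in every cell. Systems, animals, batches and clusters were used as the authors' cell table gives them, and the meaning of its flag on 20 cells was not given in the sources used here.

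Cells are not replicates, so raw counts were summed per animal and system. One of the 20 animal identifiers held cells of more than 1 system. Its auditory cells (auditory replicate 5) and its visual cells (visual replicate 1) had different sort dates, so it is unclear whether they come from 1 animal, and they were kept as separate sums, which makes 21. Of the 21 sums, 14 shared their sort date with another sum of the same system. Sums of fewer than 10 cells were left out (5 for anchor classes). The median UMI count per cell was 89468 ± 45961 in auditory sums (mean ± SD), 132807 ± 70785 in motor, 112910 ± 45386 in prefrontal, 113271 ± 28179 in somatosensory and 69226 ± 10361 in visual sums. No filter on cells was applied beyond the authors' own. No doublet caller was run, because the cells were picked by hand; 174 cells with 3 or more detected markers of another cell type (99 astrocyte, 69 oligodendrocyte, 15 microglia, 0 endothelial or mural, 0 GABA neuron) were left out in an alternative, which kept 1798 cells. Cells were put in a class by whichever of Tnnt1, Necab1 and Calb2 had the highest CPM; 73 cells with none of them or a tie had no class.

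Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors (0.956 to 1.06 for the system sums, 0.935 to 1.08 for the class sums), filterByExpr, a dispersion that follows a trend over the mean count, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Systems were compared with sequencing batch as a covariate on 14 residual degrees of freedom, each system against the mean of the other 4. Anchor classes were compared with each animal and system as a block, because the classes come from the same animals, on 57 sums (18 Calb2, 20 Necab1 and 19 Tnnt1) and 35 residual degrees of freedom; the 3 anchor genes were left out of the counts of genes. The authors' clusters within a system were compared with the animal as a block. For their 9 clusters over all systems this block left the model without full rank, so batch was the covariate. The biological coefficient of variation was 0.52 for the system sums and 0.727 for the class sums. Fixed before the data were examined were the tests, the anchor genes, 34 gene lists, the alternatives and the rule for named genes. That rule takes, per main contrast, the 10 genes with the largest fold up and the 10 with the largest fold down at an adjusted p under 0.05 and a mean of at least 10 CPM, without gene models that have no name; any member of a fixed list may be named too. Results for some genes that this rule takes are not reported here.

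The first choice of dispersion, 1 value for all genes, was replaced by the trend after its counts on the real data had been seen. On simulated data with 200 changed genes it gave 24.9% and 30.5% false calls in the Calb2 minus Tnnt1 and the Necab1 contrast, against 0 and 1.44% with the trend. In the auditory contrast it gave 4.96% false calls, against 3.4% with the trend. The simulated counts were drawn with the trend as their spread and without animal or batch effects. They therefore favour the trend and cannot show which choice suits the real data. The single dispersion was kept as an alternative. With the trend, the test on simulated data for the auditory contrast (16537 genes, 21 sums) recovered 28 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 3.4% false calls. For the visual contrast (16529 genes) it recovered 7, 43 and 58, with 5.26% false calls; for Calb2 minus Tnnt1 (15573 genes, 57 sums) 17, 42 and 61; and for Necab1 against the others (15593 genes) 25, 48 and 64. A fold of 1.5 was thus often missed at this depth and number of animals. A simulated changed list was found by camera and by fry in each of these contrasts, and 0 of 30 random lists were called.

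The 34 lists cover markers of other cell types (astrocyte, oligodendrocyte and its precursor, microglia, endothelial and mural, ependymal and choroid, blood, GABA neuron, reticular nucleus, habenula, cortical glutamatergic neuron), thalamic groups (relay identity, midline and intralaminar, axis anchors, matrix and core), functional groups (fast firing, burst and pacemaker channels, neuropeptides, modulatory receptors, immediate early genes, heat shock genes) and families (potassium, sodium and calcium channels, glutamate and GABA-A receptors, cadherins, protocadherins, ephrins, semaphorins, synaptotagmins, ribosomal proteins, the respiratory chain and mitochondrial transcripts). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 57 list calls with the preset correlation, 12 held with an estimated one. Anchor genes were correlated across the cells of each sum (Spearman's rho on log-scaled counts per cell, sums of at least 20 cells). The mean rho was tested by exact sign flips, or by 100000 resamples over all 21 sums, with scipy 1.17.1 under Python 3.11.15. Gene positions are from GENCODE vM21 on GRCm38, matched by symbol.

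Alternatives were DESeq2 1.42.0 as the test, its size factors, no filter on low counts, cells with at least 43646 UMIs (1637 cells), cells thinned to 20000 UMIs, a doubled minimum of cells, stricter anchor classes (534 cells), leaving out cells with markers of another type, each replicate or each batch, and other covariates. Chosen after the data were examined were the cells summed per sort date and system (14 sums), no batch term, 1 dispersion for all genes, leaving out the cells with the authors' flag, and the contrast of Necab1- with Tnnt1-anchored cells. Spike-ins were left out of all tests. Overlaps of calls between systems are not reported, because each system is part of the reference of the others.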

Results

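Neurons of the mouse thalamus were collected by hand after a retrograde label, an agent carried from axon endings back to the cell body, had marked them by the cortical system they project to. The deposited table held counts of unique molecular identifiers (UMIs, each standing for 1 captured transcript) in 1972 cells from 26 plates and 3 sequencing batches, over 36589 genes and 90 spike-in RNAs. A cell held 20509 to 683775 UMIs (median 87292) and 2504 to 8720 detected genes. Cells were summed per animal and system, which gave 21 sums: 5 auditory (380 cells), 5 motor (484), 4 prefrontal (388), 3 somatosensory (285) and 4 visual (435). The sums held 4317156 UMIs (auditory replicate 5) to 20322775 UMIs (prefrontal replicate 3), and the plates 2056420 to 17253430. Each sum was 1 replicate, so p-values rest on the spread between animals. Levels are CPM, the counts of a gene scaled to the same total per sum, mean ± SD over the sums of a group, and differences are log2 fold changes ± SE. All somatosensory sums came from batch 2 and all visual sums from batch 3, whereas auditory, motor and prefrontal sums came from all 3 batches. Of 13 sort dates, 12 held cells of 1 system, and each system was sorted on 3 dates (2 for somatosensory neurons).

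The first comparison asked which genes distinguish the 5 projection systems. Nts, which encodes the peptide neurotensin, led in auditory neurons. Syt2, a calcium sensor of fast transmitter release, led in motor neurons, and Slc30a3, the transporter that loads zinc into synaptic vesicles, in prefrontal neurons. Nr2f2, a nuclear receptor of developing tissues, led in somatosensory neurons, and Cntn5, a contactin of the cell surface, was among the leading genes of visual neurons. In GRCm38 (mm10) with GENCODE vM21, Nts lies on chromosome 10, 102481756 to 102490486, minus strand, and Slc30a3 on chromosome 5, 31086106 to 31108237, minus strand. Nr2f2 lies on chromosome 7, 70351944 to 70366735, minus strand, and Cntn5 on chromosome 9, 9660891 to 10904775, minus strand. Of 17211 genes tested over the 21 sums, 2173 differed among the systems in edgeR's quasi-likelihood test with sequencing batch in the model and a Benjamini-Hochberg threshold of 0.05. That count was 1317 with cells summed per sort date and system (14 sums), 1164 and 1343 without batches 1 and 3, and 3357 with no filter on low counts. Against the mean of the other 4 systems, 1371 genes changed in auditory neurons (736 higher, 635 lower; 317 higher and 392 lower without auditory replicate 5), 673 in motor neurons (399 higher, 274 lower; 542 higher and 568 lower with DESeq2) and 1578 in prefrontal neurons (894 higher, 684 lower). Only 40 passed in somatosensory neurons (6 higher, 34 lower) and 25 in visual neurons (8 higher, 17 lower), the systems with sums from 1 batch. Within batches 1, 2 and 3 alone, 136, 188 and 220 genes passed in auditory, 517, 2 and 522 in motor and 547, 89 and 55 in prefrontal neurons. Auditory neurons in batch 3, motor neurons in batch 2 and prefrontal neurons in batches 2 and 3 had 1 sum each, which is there assumed to vary like the sums of the other systems. In the same order 97.3%, 99.9% and 97.4% of the auditory calls on all sums kept their direction, 100%, 99.1% and 100% of the motor calls, and 99.8%, 99.0% and 96.5% of the prefrontal calls. These shares are partly built in, because the genes were chosen on the sums of all batches. Within batch 2 alone 115 genes passed in somatosensory neurons, 31 of the 40 among them, and within batch 3 alone 163 in visual neurons, 23 of the 25 among them. Both fits rest on the same sums of that system as the main ones.

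**Figure D1:**
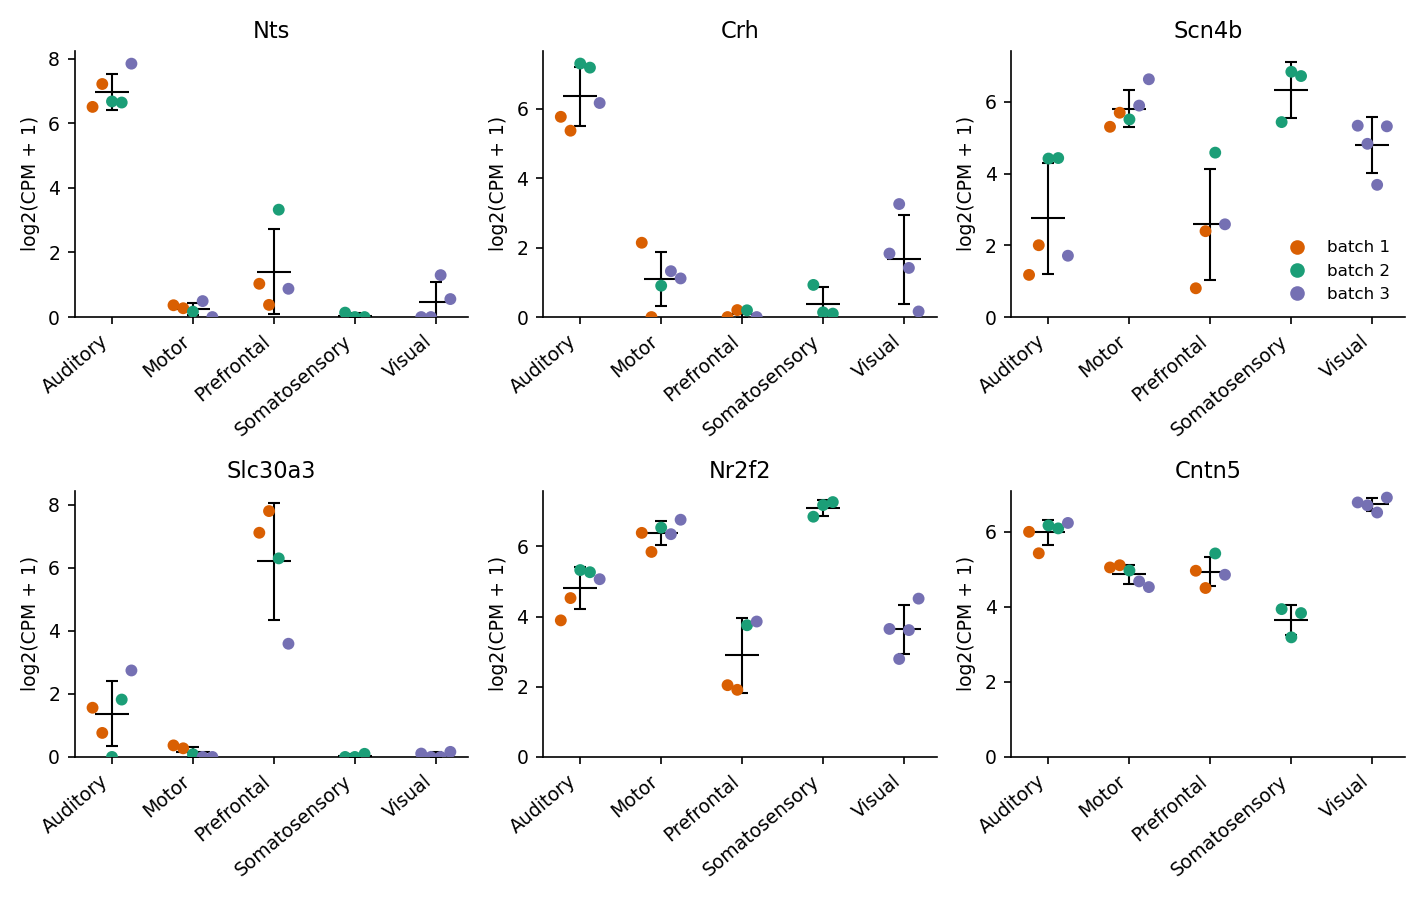
CPM of Nts, Crh, Scn4b, Slc30a3, Nr2f2 and Cntn5 per animal sum (log2 of CPM plus 1) in the 5 projection systems, with points coloured by sequencing batch and black bars for mean ± SD (n = 3 to 5 sums). The 5 auditory sums lie above the sums of the other systems for Nts, and the 4 prefrontal sums for Slc30a3.

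Auditory neurons, summed per animal, held more RNA of several neuropeptide genes. Nts averaged 133 ± 58.1 CPM in auditory sums (n = 5) against 0.206 ± 0.156 in motor (n = 5) and 2.80 ± 4.16 in prefrontal sums (n = 4). Its log2 fold over the mean of the other systems was 8.96 ± 0.53 (adjusted p = 2.7e-09). Crh, which encodes corticotropin-releasing hormone, rose by 7.04 ± 0.58 (adjusted p = 1.5e-07). Grp, gastrin-releasing peptide, rose by 6.69 ± 0.82, Cartpt by 6.11 ± 0.59 and Adcyap1, the precursor of PACAP, by 4.10 ± 0.41 (adjusted p = 1.8e-06). These transcripts lay in a part of the cells. A UMI of Nts was found in 70 of the 380 auditory cells (18.4%), and 96.0% of its auditory UMIs lay in the authors' auditory cluster 3, which has 63 cells. That cluster held 100% of the auditory UMIs of Grp (in 14 cells), 93.5% of those of Cartpt, 82.7% of Adcyap1 and 75.5% of Crh, given as a description, since it was made from the same counts. In 1 of the 5 auditory sums, replicate 5, Cartpt stood at 361 CPM against 25.1 to 110 in the others. Calb2, which encodes the calcium-binding protein calretinin, averaged 1037 ± 389 CPM and rose by 3.11 ± 0.44 (adjusted p = 0.00012). Nrgn, the calmodulin-binding neurogranin, rose by 5.55 ± 0.47, and Gbx2, a homeobox gene of the thalamus, by 1.64 ± 0.22. Gsg1l and Cnih3, both auxiliary subunits of AMPA receptors, fell (log2 folds of -5.93 ± 0.78 and -3.73 ± 0.45). So did the neurofilament genes Nefh (-1.25 ± 0.17) and Nefm (-1.21 ± 0.17).

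Of the 15 neuropeptide genes tested, 6 were higher and 2 lower in auditory neurons, and 6 and 3 adjusted over the list alone (camera adjusted p = 7.8e-06, adjusted p = 0.018 with an estimated correlation). Of 13 midline and intralaminar markers, 7 rose and none fell, among them Calb2 and the peptide genes Nts, Cartpt and Grp, which are on both lists. Adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 2.3e-07, adjusted p = 0.0028 with an estimated correlation). Among 28 receptors for neuromodulators, 8 rose, such as the adrenergic Adra2a (6.03 ± 1.03), and 12 rose adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.010 with an estimated correlation). The fast firing list holds 14 genes of Kcna and Kcnc potassium channels, sodium channels and neurofilaments. Of these, 8 fell, and 10 adjusted over the list alone (camera adjusted p = 4.4e-07, adjusted p = 0.25 with an estimated correlation). Of 89 genes of the respiratory chain, 27 fell, for example Atp5b (-0.57 ± 0.09), and 50 adjusted over the list alone (camera adjusted p = 1.2e-19, adjusted p = 0.14 with an estimated correlation). The auditory count was 709 without auditory replicate 5, 426 without batch 2 and 819 without batch 3.

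Motor neurons had more Syt2, which averaged 37.3 ± 28.5 CPM (n = 5) and rose by 4.15 ± 0.64 on the log2 scale (adjusted p = 0.00075). Pvalb, the calcium buffer parvalbumin, averaged 101 ± 37.1 CPM in motor and 4.15 ± 4.14 in prefrontal sums and rose by 2.57 ± 0.36 (adjusted p = 0.00047). Kcna1, a low-threshold potassium channel subunit, rose by 1.39 ± 0.19 and the heavy neurofilament gene Nefh by 1.2 ± 0.16. Abhd12b rose by 2.22 ± 0.23 (adjusted p = 2.8e-05). In motor replicate 3 it stood at 467 CPM against 186 to 255 in the other motor sums. Of the 14 fast firing genes, 12 rose and none fell, among them Nefm (1.09 ± 0.16), and all 14 rose adjusted over the list alone (camera adjusted p = 3.5e-19, adjusted p = 0.11 with an estimated correlation). Of 81 ribosomal protein genes, 11 fell and 0 rose (23 and 1 adjusted over the list alone, camera adjusted p = 8.6e-17, adjusted p = 0.26 with an estimated correlation). Of the 28 modulatory receptors, 7 fell, and 9 adjusted over the list alone (camera adjusted p = 0.0069, adjusted p = 0.17 with an estimated correlation).

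In batch 2, where the 1 motor sum was set against 6 others that included the somatosensory ones, Kcna1 stood at 152 against 148 CPM and Pvalb at 50.3 against 41.9. Within batch 2 alone 2 genes passed. The motor count was 414, 419 and 388 without motor replicates 1, 2 and 5. It was 156 with cells summed per sort date, 407 with no batch term, 1037 with 1 dispersion for all genes, 1110 with DESeq2 and 1104 with no filter, and 156, 1152 and 205 without batches 1, 2 and 3.

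In prefrontal neurons Slc30a3 averaged 111 ± 89.1 CPM (n = 4), against 2.17 ± 2.20 in auditory and 0.112 ± 0.131 in motor sums (n = 5 each). Its log2 fold was 8.93 ± 0.65 (adjusted p = 6.6e-08). Within batches 1, 2 and 3 it stood at 179 against 0.785, 77.4 against 0.443 and 11 against 0.840 CPM in the other systems, with 1 prefrontal sum each in batches 2 and 3. Fbln1, which encodes the matrix protein fibulin 1, rose by 7.54 ± 0.50 (adjusted p = 2.3e-08), Gpx3, a secreted glutathione peroxidase, by 6.45 ± 0.57, and C1ql3, a secreted synaptic protein, by 6.20 ± 0.46. The peptide gene Gal (galanin) rose by 3.95 ± 0.43 (adjusted p = 5.0e-06). Oprk1 and Cnr1, the kappa opioid and cannabinoid receptors, rose by 6.48 ± 0.72 and 5.82 ± 0.78, and Necab1, a neuronal calcium-binding protein, by 1.55 ± 0.28. Hpca, the calcium sensor hippocalcin, fell (log2 fold -2.85 ± 0.36, adjusted p = 2.6e-05), as did Pvalb (-3.25 ± 0.51), Kcna1 (-1.83 ± 0.24) and Kcnc1 (-1.0 ± 0.13).

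Of the 14 fast firing genes, 13 fell in prefrontal neurons and none rose, and all 14 fell adjusted over the list alone (camera adjusted p = 1.9e-17, adjusted p = 0.060 with an estimated correlation). Of 28 modulatory receptors, 11 rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.035 with an estimated correlation). Of 13 midline and intralaminar markers, 6 rose, such as Gal and Lypd6b (6.39 ± 0.92), and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 8.2e-05, adjusted p = 0.033 with an estimated correlation). Of 81 ribosomal protein genes, 18 rose, for example Rpl3 by 0.63 ± 0.10, and 20 adjusted over the list alone (camera adjusted p = 6.2e-08, adjusted p = 0.63 with an estimated correlation). Of 10 oligodendrocyte markers, 5 were lower, and 7 adjusted over the list alone (camera adjusted p = 0.00077, adjusted p = 0.61 with an estimated correlation). The authors had marked 20 cells with a flag, of which 0 were prefrontal. Without those cells 0 of 6 markers still tested were lower and 1, Mbp, was higher (3 at an unadjusted p under 0.05 in edgeR's test), and the list median went from -5.81 to 0.13. DESeq2 was not run without those cells. The myelin gene Mobp (-5.57 ± 1.66) stood at -0.58 without them and no longer passed. Its call also ended without any 1 of prefrontal replicates 1 to 4, auditory replicate 2, motor replicates 1 and 2, somatosensory replicate 1, visual replicate 4 and batches 1 to 3. The prefrontal count was 452 without batch 1 and 1036 without batch 2.

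Somatosensory neurons had more Nr2f2, at 137 ± 20.2 CPM (n = 3) against 83.8 ± 18.6 in motor and 7.98 ± 5.83 in prefrontal sums. Its log2 fold was 2.28 ± 0.35 (adjusted p = 0.0053). Rgs4, a regulator of G protein signalling, rose by 1.31 ± 0.18 and Pitpnc1, a phosphatidylinositol transfer protein, by 1.20 ± 0.18 (adjusted p = 0.0015 and 0.0032). Cntn5 averaged 11.9 ± 3.32 CPM and fell (log2 fold -2.28 ± 0.26, adjusted p = 0.00013). Dab1, an adaptor of reelin signalling, was at 0 in all 3 somatosensory sums (adjusted p = 0.0029). With a floor of 3 counts over the group's 35201582 UMIs (0.0852 CPM) it was at least 185-fold lower than in visual sums (15.8 ± 3.04 CPM), at least 508-fold lower than in auditory sums and at least 119.5-fold lower than in prefrontal sums. Motor sums were also low, at 0.297 ± 0.320 CPM, at least 3.49-fold above the somatosensory floor, and this pair was not tested alone. Of the 14 fast firing genes 1 rose and 4 adjusted over the list alone (camera adjusted p = 1.3e-10, adjusted p = 0.12 with an estimated correlation). Of 89 respiratory chain genes 0 rose in edgeR's test over all genes and 15 adjusted over the list alone (camera adjusted p = 1.2e-23, adjusted p = 0.10 with an estimated correlation). The calls of Nr2f2 and Rgs4 ended with cells summed per sort date, which left 6 genes. The count was 14, 12 and 21 without auditory, motor and prefrontal replicate 3, and 8 and 16 without somatosensory replicates 2 and 3. Without batch 3 it was 69. The balance of 6 higher and 34 lower calls also moved. It was 243 higher and 215 lower with no batch term, 65 higher and 64 lower with 1 dispersion for all genes, 42 higher and 40 lower without batch 1, 150 higher and 248 lower with no filter and 75 higher and 196 lower with DESeq2.

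Visual neurons had more Cntn5, which averaged 105 ± 12 CPM (n = 4) and rose by 2.05 ± 0.23 (adjusted p = 0.00012), and the teneurins Tenm2 and Tenm3, which bind partners across the synapse, rose by 1.31 ± 0.15 and 1.27 ± 0.18 (adjusted p = 0.00016 and 0.0016). Heg1, a membrane protein of vessel formation, rose by 2.55 ± 0.34 (adjusted p = 0.00092). Car8, a protein related to carbonic anhydrases, stood at 0.202 ± 0.174 CPM against 36.0 ± 17.1 in motor sums and fell (log2 fold -7.27 ± 0.78, adjusted p = 0.00012). Aldoc, the brain form of aldolase, fell (log2 fold -2.09 ± 0.31, adjusted p = 0.0039), with visual replicate 3 at 19.2 CPM against 26.6 to 27.6 in the other visual sums. Of 13 midline and intralaminar markers 1 fell, and 5 adjusted over the list alone (camera adjusted p = 0.0024, adjusted p = 0.12 with an estimated correlation). The visual count was 9, 16 and 12 without auditory replicate 5, motor replicate 5 and prefrontal replicate 4, and 12, 14 and 12 without visual replicates 1, 2 and 3. It was 116 with no batch term (56 higher and 60 lower), 186 with DESeq2 and 270 with no filter, and without batches 1 and 2 the calls were 34 higher and 23 lower, and 30 higher and 31 lower.

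**Figure D2:**
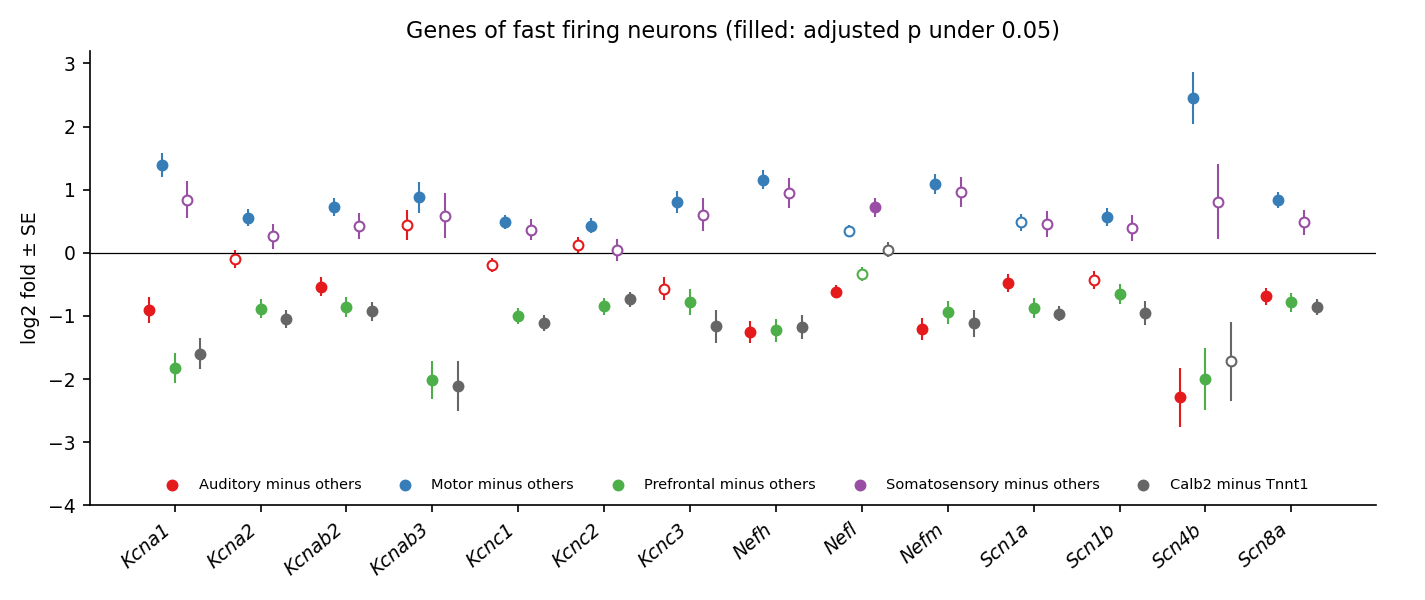
Log2 fold changes ± SE of the 14 fast firing genes in each comparison named in the legend, with filled symbols for adjusted p under 0.05 (edgeR quasi-likelihood test) and open symbols otherwise. The motor folds lie above 0 and the prefrontal and Calb2 minus Tnnt1 folds lie mostly below 0.

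The next comparisons asked whether neurons within a system are ordered by 3 anchor genes, fixed before the data were examined: Tnnt1, a troponin subunit, Necab1 and Calb2. On GRCm38 Tnnt1 lies on chromosome 7, 4504570 to 4516382, minus strand, and Necab1 on chromosome 4, 14952245 to 15149794, minus strand. Calb2 lies on chromosome 8, 110137502 to 110168210, minus strand. Each cell was put in the class of its anchor with the highest CPM, which gave 756 Tnnt1, 532 Necab1 and 611 Calb2 cells. Of these 1899 cells, 384 held a second anchor within 2-fold of the first and 587 held UMIs of 1 anchor only. Tnnt1-anchored cells made up 81.3 ± 9.93% of somatosensory cells (mean ± SD, n = 3), 39.5 ± 6.11% of visual (n = 4) and 38.4 ± 16.2% of motor cells (n = 5). They were 24 ± 13.8% of auditory (n = 5) and 9.68 ± 7.23% of prefrontal cells (n = 4). Calb2-anchored cells made up 62.8 ± 16.4% of auditory, 49.4 ± 27.0% of prefrontal, 35.2 ± 6.83% of visual, 10.1 ± 1.41% of motor and 1.84 ± 0.712% of somatosensory cells. Necab1-anchored shares were highest in motor (43.7 ± 15.8%) and prefrontal cells (39.2 ± 25.3%). None of the 30 two-sided exact permutation tests between pairs of systems passed after adjustment. The Calb2 share in auditory against motor cells, higher in 5 of 5 sums, gave exact p = 0.0079, adjusted p = 0.068, where the exact p is the smallest that 5 sums against 5 can give. With every cell thinned to 20000 UMIs, the Calb2 share of the cells with a class was 64.6 ± 17.5% in auditory and 8.39 ± 4.64% in motor neurons (62.9 ± 16.2% and 11 ± 1.55% with all UMIs). Thinning left 13 auditory and 99 motor cells without a class.

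**Figure D3:**
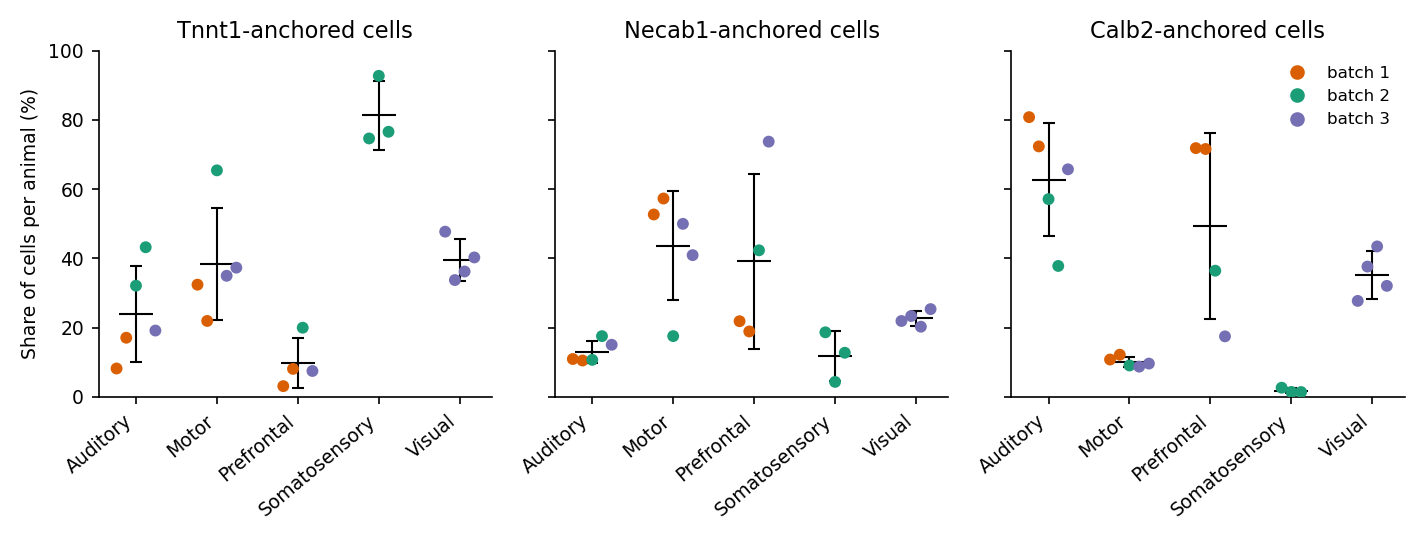
Percent of the cells of each animal sum whose highest anchor gene was Tnnt1, Necab1 or Calb2, in the 5 projection systems, with points coloured by sequencing batch and black bars for mean ± SD (n = 3 to 5 sums). The Tnnt1 share is highest in the somatosensory sums (81.3%) and the Calb2 share in the auditory sums (62.8%).

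Across the cells of a sum, Tnnt1 was negatively correlated with Calb2 (Spearman's rho -0.34 ± 0.30, mean ± SD of 21 sums, 18 below 0) and with Necab1 (-0.23 ± 0.16, 19 below 0). Necab1 was positively correlated with Calb2 (0.20 ± 0.19, 2 below 0). The sign-flip permutation tests over the 21 sums were two-sided. For Tnnt1 and Calb2 they gave p = 9e-05 (adjusted p = 0.00054 among 18 tests) and for Necab1 and Calb2 p = 2e-05 (adjusted p = 0.00018). Tnnt1 and Necab1 gave p = 1e-05, the smallest that 100000 resamples can give (adjusted p = 0.00018). The mean rho of Tnnt1 and Calb2 was -0.57 ± 0.17 in auditory (n = 5), -0.60 ± 0.07 in visual (n = 4) and -0.44 ± 0.19 in prefrontal neurons (n = 4). It was -0.05 ± 0.10 in motor (n = 5) and 0.05 ± 0.18 in somatosensory neurons (n = 3). With 3 to 5 sums the exact tests within a system cannot go below 0.0625 to 0.25.

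Calb2-anchored neurons, compared with Tnnt1-anchored neurons of the same animals, had more Prph, which encodes the intermediate filament peripherin (80.1 ± 130.1 against 0.286 ± 0.525 CPM, 18 and 19 sums). Its log2 fold was 7.32 ± 0.93 (adjusted p = 2.3e-07). The vesicle GTPase gene Rab3b rose by 6.42 ± 0.82, Nrgn by 5.81 ± 0.70 and Kcnip1, a modulator of A-type potassium channels, by 5.70 ± 0.76. Calb1, which encodes the calcium buffer calbindin, rose by 1.43 ± 0.16 (adjusted p = 1.0e-08). Tnnt1-anchored neurons had more Prkcd, a protein kinase C of sensory thalamus (2413 ± 652 against 846 ± 703 CPM), with a log2 fold of -1.87 ± 0.22 from Tnnt1 to Calb2 cells (adjusted p = 2.2e-08). They also had more Rora, a nuclear receptor of thalamic neurons (log2 fold -1.08 ± 0.08, adjusted p = 1.1e-12). Car4, a carbonic anhydrase, fell (-3.12 ± 0.42), as did Abhd12b (-2.71 ± 0.39) and Kcna1 (-1.60 ± 0.25). On GRCm38, Prph lies on chromosome 15, 99055174 to 99058978, plus strand, and Rab3b on chromosome 4, 108879063 to 108943324, plus strand. Of 16662 genes tested over 57 sums with the animal as a block, 1600 differed (903 higher and 697 lower in Calb2-anchored cells). Within batches 1, 2 and 3 alone 1, 525 and 608 genes passed. Of the 1600, 98.8%, 99.7% and 100% of those tested there kept their direction, which is partly built in because they were chosen on the same sums.

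Of the 14 fast firing genes, 12 fell from Tnnt1- to Calb2-anchored cells and none rose (13 adjusted over the list alone, camera adjusted p = 2.3e-22, adjusted p = 0.0028 with an estimated correlation). Among them were Kcnc1 (-1.11 ± 0.13), Scn1a (-0.96 ± 0.12) and Nefh (-1.17 ± 0.19). Of 12 genes of thalamic relay identity, 7 fell, such as the vesicular glutamate transporter gene Slc17a7 (-1.86 ± 0.41) and the transcription factor gene Lef1 (-0.90 ± 0.15), and none rose. A total of 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.0012 with an estimated correlation). Of 12 midline and intralaminar markers, 8 rose, and 9 adjusted over the list alone (camera adjusted p = 3.3e-05, adjusted p = 0.057 with an estimated correlation). Of 28 modulatory receptors, 7 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.24 with an estimated correlation). Oprk1 rose by 5.58 ± 0.94 and the histamine receptor gene Hrh1 by 4.78 ± 0.96. Of 16 neuropeptide genes, 5 rose (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.25 with an estimated correlation). Adcyap1 was among them (3.73 ± 0.82), though its call ended without batch 2. Of 81 ribosomal protein genes, 42 rose, with Rpl3 up by 0.74 ± 0.11, and 53 adjusted over the list alone (camera adjusted p = 2.3e-22, adjusted p = 0.064 with an estimated correlation). Of 10 oligodendrocyte markers, 3 were higher in Calb2-anchored cells (9 adjusted over the list alone, camera adjusted p = 0.00031, adjusted p = 0.28 with an estimated correlation). Without the 20 cells with the authors' flag, 0 of the 5 members still tested passed in edgeR's test (1 at an unadjusted p under 0.05, while DESeq2 was run with those cells only and gave 3 of 10), and the list median went from 2.87 to 0.39. The number passing was 1 without auditory replicate 2 or 5, motor replicate 1, visual replicate 1 or 2 or batch 3, with the minimum of cells doubled or with no animal block. It was 8 without visual replicate 4, 9 with no filter and 10 with 1 dispersion for all genes. In edgeR's test it was 0 of 5 without cells showing another type (0 at an unadjusted p under 0.05). With classes limited to cells with at least 3 UMIs of 1 anchor and none of the others, 534 cells remained and 30 genes passed (5 higher and 25 lower). In these classes the oligodendrocyte markers lay on the other side, with all 10 folds below 0 (-10.75 to -3.32, median -7.87), and 0 passed in edgeR's test (1 at an unadjusted p under 0.05). The count of genes over all classified cells was 769 and 652 without batches 2 and 3, and 2753 with 1 dispersion for all genes.

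Necab1-anchored neurons, set against the mean of both other classes, had more Col25a1, which encodes a membrane collagen (223 ± 150.4 CPM in 20 sums against 69.3 ± 48.8 in Calb2 and 103 ± 103 in Tnnt1 cells). Its log2 fold was 1.57 ± 0.30 (adjusted p = 0.00063). The glutamate transporter gene Slc1a2 rose by 0.88 ± 0.11 (adjusted p = 2.4e-06) and the AMPA receptor gene Gria1 by 0.79 ± 0.14. Necab3, a relative of Necab1, fell (log2 fold -1.11 ± 0.19, adjusted p = 0.00023). Of 86 respiratory chain genes, 42 fell and none rose, such as Atp5d (-0.28 ± 0.05) and Cox6b1 (-0.30 ± 0.05), and 63 fell adjusted over the list alone (camera adjusted p = 2.5e-36, adjusted p = 0.0061 with an estimated correlation). Of 12 relay identity genes, 3 rose, the vesicular glutamate transporter gene Slc17a6 among them (0.26 ± 0.07), and 5 adjusted over the list alone (camera adjusted p = 5.4e-05, adjusted p = 0.0061 with an estimated correlation). The call of Slc17a6 ended with thinned cells and without batch 1 or 3. Of 26 glutamate receptor genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 7.4e-05, adjusted p = 0.0061 with an estimated correlation), Gria1 among those that rose. In all, 746 genes differed (285 higher, 461 lower; 385 higher and 367 lower with DESeq2 size factors, 660 higher and 690 lower with DESeq2 as the test and 879 higher and 818 lower with 1 dispersion), of which 99.9%, 99.9% and 99.7% of those tested kept their direction within batches 1, 2 and 3, again partly built in. Within these batches alone 9, 2 and 25 genes passed. The count was 429, 298 and 210 without batches 1, 2 and 3, and 1697 with 1 dispersion for all genes. The stricter classes gave 0 genes in edgeR's test (995 at an unadjusted p under 0.05; DESeq2 was run on all anchored cells only and gave 1350). Directly against Tnnt1-anchored cells, a contrast added after the data were examined, 638 genes differed (305 higher, 333 lower; 357 higher and 250 lower with DESeq2 size factors). That count was 228 and 237 without batches 2 and 3, 69 with the stricter classes, 396 with thinned cells, 1023 with DESeq2 and 1343 with 1 dispersion for all genes. Kcna1 (-1.63 ± 0.24) and Nefm (-1.2 ± 0.20) fell. In this contrast 10 of the 14 fast firing genes fell (13 adjusted over the list alone, camera adjusted p = 1.2e-14, adjusted p = 0.036 with an estimated correlation). Likewise 44 of 86 respiratory chain genes fell (56 adjusted over the list alone, camera adjusted p = 8.1e-39, adjusted p = 0.013 with an estimated correlation).

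A further comparison asked whether the same genes separate the classes in each system. Between Calb2- and Tnnt1-anchored cells Rora had a log2 fold of -1.06 ± 0.11 in auditory, -1.79 ± 0.14 in prefrontal and -0.98 ± 0.12 in visual neurons, and stood at -0.63 ± 0.11 in motor neurons. The folds differed between systems (adjusted p of the interaction = 0.0081). Prkcd gave -2.39 ± 0.23, -0.64 ± 0.21, -3.82 ± 0.31 and -1.34 ± 0.24 in auditory, motor, prefrontal and visual neurons (interaction adjusted p = 0.00016). Cartpt gave 9.35 ± 0.80, -2.02 ± 1.1, 4.66 ± 1.20 and 1.07 ± 0.88 (adjusted p = 0.00016). In the same order Rab3b gave 7.49 ± 0.82, -2.61 ± 1.55, 8.61 ± 1.02 and 5.67 ± 1.04 (adjusted p = 0.016). Fitted per system, 281 genes passed in auditory (5 animals), 312 in prefrontal (3), 80 in visual (4) and 1 in motor neurons (5). In motor neurons Prph rose by 9.24 ± 0.94 (edgeR adjusted p = 0.024), and 1176 genes had an unadjusted p under 0.05. Of 15734 genes tested, the difference between classes depended on the system for 51 (edgeR F test of the interaction, 34 sums, 1089 at an unadjusted p under 0.05). Across genes, which are not independent replicates, the folds correlated between auditory and prefrontal neurons with Pearson's r = 0.44 (Spearman's rho 0.36), auditory and visual with 0.37 (0.30), and prefrontal and visual with 0.35 (0.30). The other pairs gave 0.25 (0.27) for motor and visual, 0.08 (0.12) for motor and prefrontal and 0.05 (0.10) for auditory and motor neurons. Among genes above 10 CPM in both systems, Pearson's r was 0.50, 0.48 and 0.46 for the first 3 pairs. For the motor pairs it was 0.38, 0.26 and 0.24, in the order given. Of the genes called in auditory, prefrontal and visual neurons, 88.6%, 89.1% and 98.7% had the same sign in motor neurons.

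Between Necab1- and Tnnt1-anchored cells of the same animals, 51 genes passed in motor, 38 in prefrontal, 108 in somatosensory (2 animals), 11 in visual and 4 in auditory neurons. The auditory genes, named after their values were seen, were Nefm (-1.60 ± 0.22), Pcp4 (-0.92 ± 0.12), Pcp4l1 (-1.69 ± 0.27) and Prkcd (-1.70 ± 0.18). For 5 of 15647 genes the difference depended on the system (633 at an unadjusted p under 0.05). These were Col25a1, Cox6a2, Dynlt3, Lsamp and Syn2, also named after their values were seen.

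**Figure D4:**
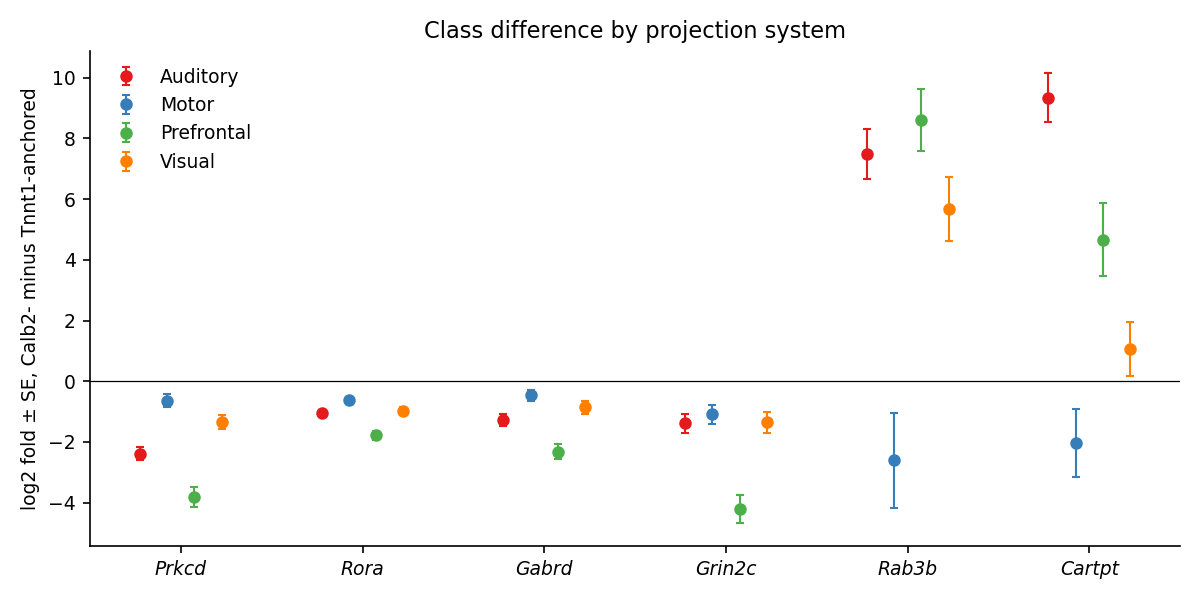
Log2 fold change ± SE between Calb2- and Tnnt1-anchored cells of the same animals, for the 6 genes named on the plot whose fold differed between systems. The folds of the 4 systems come from 1 model with the interaction (34 sums). Rab3b lies above 0 in auditory, prefrontal and visual neurons and at -2.61 in motor neurons.

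The authors' annotation also placed 1952 cells in 17 clusters within systems and in 9 clusters over all systems. Over all systems, Tnnt1-anchored cells were 144 of the 174 cells of cluster 1 and 251 of the 312 of cluster 2, and Necab1-anchored cells 166 of 259 in cluster 7. Calb2-anchored cells were 63 of 65 in cluster 8 and 89 of 99 in cluster 9. Cluster 3 held 313 visual cells among 338, cluster 5 held 289 auditory cells among 331, and all 99 cells of cluster 9 were prefrontal and came from 2 animals of batch 1. On sums per animal and cluster, 4914 genes differed among the 9 clusters, and 812, 1075, 574, 718 and 296 among the clusters within the auditory, motor, prefrontal, somatosensory and visual systems. The clusters were made from the same counts, so these counts only describe them, and no gene is reported as a result of this comparison. For the 9 clusters an animal block could not be fitted, so sums of 1 animal were treated as separate and their p-values are too small. Sums of fewer than 10 cells, and animals left with 1 cluster, were not in the fits within systems. The prefrontal count therefore compares clusters 1, 2 and 4 in 2 of 4 animals (replicates 3 and 4, 244 of 388 cells). Its cluster 3, with 113 cells, was left out, because in replicates 1 and 2 no other cluster reached 10 cells. The auditory fit held replicates 2 to 5 (297 of 376 cells). The prefrontal and somatosensory clusters left 1 and 2 residual degrees of freedom. The count for the auditory clusters was 375 without cells showing another cell type, and 389, 405 and 479 without auditory replicates 3, 4 and 5. That for the motor clusters was 528, 617 and 406 without motor replicates 3, 4 and 5, and that for the visual clusters 141, 162 and 129 without visual replicates 2, 3 and 4. Without batches 2 and 3 the counts were 1945 and 2520 for the 9 clusters, 209 and 479 for the auditory and 528 and 145 for the motor clusters. DESeq2 gave 2267, 1884, 2721 and 745 for the auditory, motor, somatosensory and visual clusters, and its size factors 960 for the prefrontal ones. With 1 dispersion for all genes the prefrontal clusters gave 0 in edgeR's test (2547 at an unadjusted p under 0.05; 724 with DESeq2 as the test of the authors' cell groups: clusters of the prefrontal system).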

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

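The contrast of Necab1- with Tnnt1-anchored cells and the draws of auditory cells set beside the low-Calb2 cells were chosen after the data had been seen, and the other tests here beforehand. In 108 groups of 4 or 5 sums, 7 had 1 sum far from the rest, against about 5.40 by chance alone. Abhd12b stood at 467 CPM in motor replicate 3 against 186 to 255 in the other 4 sums, a gap of 0.754 of the range. Aldoc stood at 19.2 CPM in visual replicate 3 against 26.6 to 27.6 in the other 3 sums, a gap of 0.877 of the range. Cartpt stood at 361 CPM in auditory replicate 5 against 25.1 to 109.9 in the other 4 sums, a gap of 0.747 of the range. Gad2 stood at 20.9 CPM in auditory replicate 5 against 0 to 2.63 in the other 4 sums, a gap of 0.874 of the range. Gad2 stood at 0.0580 CPM in motor replicate 1 against 0 in the other 4 sums, a gap of 1.00 of the range. Gpx3 stood at 1.40 CPM in motor replicate 5 against 0 to 0.116 in the other 4 sums, a gap of 0.917 of the range. Htr1b stood at 0.546 CPM in motor replicate 4 against 0 to 0.124 in the other 4 sums, a gap of 0.773 of the range.

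The difference between Calb2- and Tnnt1-anchored cells depended on the system for 51 genes, by edgeR's test of the interaction, and that between Necab1- and Tnnt1-anchored cells for 5. Of 24 splits of the animals among the systems, only the real one gave 51 genes, and the highest other gave 1. Chance is not excluded by 24 splits, which count animals as exchangeable although many animals of a system shared a sort date. For Cartpt (adjusted p = 0.00016) and Prkcd (adjusted p = 0.00016) the folds are in the report, as are those of Rab3b (adjusted p = 0.016) and Rora (adjusted p = 0.0081). Gabrd, a delta subunit of GABA-A receptors, gave -1.29 ± 0.19 in auditory, -0.47 ± 0.19 in motor, -2.33 ± 0.25 in prefrontal and -0.86 ± 0.21 in visual neurons (adjusted p = 0.012), and Grin2c, an NMDA receptor subunit, -1.39 ± 0.31 in auditory, -1.09 ± 0.31 in motor, -4.22 ± 0.46 in prefrontal and -1.36 ± 0.34 in visual neurons (adjusted p = 0.012). Spike-in RNAs, which no comparison used, took 6.40% of all UMIs.

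Only 1 gene separated Calb2- from Tnnt1-anchored motor neurons, against 281 in auditory neurons. Fewer Calb2-anchored motor cells is argued against as the whole explanation: with auditory cells drawn down to the motor numbers, auditory neurons still gave 41 to 137 genes (median 93.5) in 20 draws. With auditory Calb2-anchored cells limited to those at or below 471 CPM of Calb2, the upper quartile of the motor class, 8 genes passed, whereas random draws of as many auditory cells gave 35 to 120. A candidate explanation is therefore that Calb2-anchored motor cells hold little Calb2, so that the class there is a weaker contrast. A difference between the nuclei that project to each cortex stays open and was not tested.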

How the results depend on the processing

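The cells summed per sort date, the fits without a batch term, with 1 dispersion or without the cells that carry the authors' flag, and the contrast of Necab1- with Tnnt1-anchored cells were chosen after the data were examined. Of 483 values of main results under the alternatives, 389 lay within 1.5 times the main one or within its spread and 94 did not. Most of these values are counts, which have no direction to reverse. None of the correlations that passed changed sign. The balance of calls did turn in places. For example, 736 higher and 635 lower auditory calls became 317 and 392 without auditory replicate 5. Likewise 399 higher and 274 lower motor calls became 542 and 568 with DESeq2. Of 147 gene and contrast pairs followed, the same side and direction was kept by 147 with DESeq2 size factors, 147 with no filter and 145 with DESeq2 as the test, by 70 of 92 with cells summed per sort date, and by 117 of 147, 112 of 136 and 103 of 137 without batches 1, 2 and 3. Stricter anchor classes kept 2 of 52. DESeq2 size factors moved the median fold of all genes by at most 0.0386 and turned the median of 0 of 57 called lists.

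No paired analysis was possible because each animal identifier held cells of 1 system, except that of auditory replicate 5 and visual replicate 1, whose different sort dates leave it unclear whether they are 1 animal, so no replicate block can be fitted between systems; equal replicate numbers there only name sums. Between anchor classes the block is in the main model, and without a replicate block the counts were 1692 for Calb2-anchored against Tnnt1-anchored cells and 875 for Necab1-anchored against the other anchored cells, compared with 1600 and 746. Without that block 52 of 55 gene and contrast pairs were kept. A doubled minimum number of cells removed no sum of the systems and says nothing about them.

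Values that reversed were few. Car8 in motor neurons stood at -0.035 without batch 3. With stricter anchor classes the log2 folds were -10.75 for Mbp (Calb2 minus Tnnt1), -7.07 for Ermn, Calb2 minus Tnnt1, and -0.95 for Kcnt2, -0.12 for Cpne5, 2.27 for Pvalb, 0.25 for Ndufa10 (Necab1 against the others), none of them past the threshold. These classes hold 534 of 1899 cells; beyond that the cause was not tested.

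The main counts of genes were 2173 for all systems, 1371 for auditory, 673 for motor, 1578 for prefrontal, 40 for somatosensory, 25 for visual, 1600 for Calb2 minus Tnnt1, 746 for Necab1 against the others, 638 for Necab1 minus Tnnt1, 4914 for the 9 clusters, 812 for auditory clusters, 1075 for motor clusters, 574 for prefrontal clusters, 718 for somatosensory clusters, 296 for visual clusters. Counts that moved by over 1.5 times follow, and apart from settings that leave fewer sums, cells or genes the cause was not tested. With no filter on low counts the counts were 3357 for all systems, 1104 for motor, 398 for somatosensory, 270 for visual, 1373 for auditory clusters, 1673 for motor clusters, 1152 for prefrontal clusters, 1425 for somatosensory clusters and 729 for visual clusters. With DESeq2 as the test the counts were 1110 for motor, 271 for somatosensory, 186 for visual, 1350 for Necab1 against the others, 1023 for Necab1 minus Tnnt1, 2267 for auditory clusters, 1884 for motor clusters, 2721 for somatosensory clusters and 745 for visual clusters. With DESeq2 size factors the count was 960 for prefrontal clusters. With 1 dispersion for all genes the counts were 1037 for motor, 129 for somatosensory, 2753 for Calb2 minus Tnnt1, 1697 for Necab1 against the others, 1343 for Necab1 minus Tnnt1, 1844 for motor clusters, 0 for prefrontal clusters (2547 at an unadjusted p under 0.05 in edgeR's test, and 724 with DESeq2 as the test of the authors' cell groups: clusters of the prefrontal system) and 465 for visual clusters. With no batch term the counts were 407 for motor, 458 for somatosensory and 116 for visual. With cells summed per sort date the counts were 1317 for all systems, 156 for motor and 6 for somatosensory. Without batch 1 the counts were 1164 for all systems, 156 for motor, 452 for prefrontal, 82 for somatosensory, 57 for visual and 429 for Necab1 against the others. Without batch 2 the counts were 426 for auditory, 1152 for motor, 1036 for prefrontal, 61 for visual, 769 for Calb2 minus Tnnt1, 298 for Necab1 against the others, 228 for Necab1 minus Tnnt1, 1945 for the 9 clusters, 209 for auditory clusters and 528 for motor clusters. Without batch 3 the counts were 1343 for all systems, 819 for auditory, 205 for motor, 69 for somatosensory, 652 for Calb2 minus Tnnt1, 210 for Necab1 against the others, 237 for Necab1 minus Tnnt1, 2520 for the 9 clusters, 479 for auditory clusters and 145 for motor clusters. With thinned cells the count was 396 for Necab1 minus Tnnt1. With cells of at least 43646 UMIs the count was 472 for auditory clusters. With the minimum number of cells doubled the counts were 399 for auditory clusters and 640 for motor clusters. Without cells that show another type the count was 375 for auditory clusters. With stricter anchor classes the counts were 30 for Calb2 minus Tnnt1, 0 for Necab1 against the others (995 at an unadjusted p under 0.05 in edgeR's test, 1350 with DESeq2 on all anchored cells) and 69 for Necab1 minus Tnnt1. A minimum of 10 cells gave 0 motor genes between Calb2- and Tnnt1-anchored cells by edgeR (564 at an unadjusted p under 0.05), against 1; the mean rho of Necab1 and Calb2 in somatosensory neurons was 0.10 with thinned cells, against 0.05; and 12 list calls, against 57, held with an estimated correlation.

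Leaving out 1 replicate at a time gave 1792 to 2156 for all systems, 709 to 1501 for auditory, 388 to 750 for motor, 1110 to 1597 for prefrontal, 8 to 53 for somatosensory, 9 to 36 for visual, 1348 to 1696 for Calb2 minus Tnnt1, 546 to 829 for Necab1 against the others, 465 to 698 for Necab1 minus Tnnt1, 4218 to 5094 for the 9 clusters, 389 to 710 for auditory clusters, 406 to 969 for motor clusters, 535 to 999 for somatosensory clusters and 129 to 209 for visual clusters. The replicates behind a move of over 1.5 times are named with their counts in the report. Not fitted were the prefrontal clusters without replicate 3 or 4 or without batch 2 or 3 (too few sums), the somatosensory clusters without replicate 3 (no residual degrees of freedom) and the anchor classes without somatosensory replicate 2 (that animal gave a sum of 1 class only, so it held no pair). Depth limits which cells can be put in a class: with cells thinned to 20000 UMIs 99 motor cells had no class, against 38 with all UMIs, and 49 of 55 gene and contrast pairs of the anchor classes were kept.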

Other observations

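Chosen after the results were seen were the tests of splits for the Necab1 minus Tnnt1 contrast and for the authors' clusters, the splits of the sums per sort date, and the values without the cells that carry the authors' flag. Immediate early genes, which respond to neuronal activity, were higher in auditory neurons for 2 of 16 genes (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00077, adjusted p = 0.059 with an estimated correlation), Jun among them (0.92 ± 0.14). In motor neurons 1 fell (camera adjusted p = 0.034, adjusted p = 0.21 with an estimated correlation), and in somatosensory neurons 0 passed in edgeR's test over all genes and 4 were lower adjusted over the list alone (camera adjusted p = 0.00081, adjusted p = 0.075 with an estimated correlation). GABA-A receptor subunits went both ways: 5 rose and 3 fell in auditory neurons (camera adjusted p = 0.11), with Gabrg1 up by 3.12 ± 0.37 and Gabra4 at -0.91 ± 0.13, and 6 rose and 3 fell in prefrontal neurons (camera adjusted p = 0.22), with Gabra5 up by 2.78 ± 0.41. Between Calb2- and Tnnt1-anchored cells Gabra2 rose by 1.5 ± 0.20 and Gabrd stood at -1.10 ± 0.18; in all 2 of 14 rose and 3 fell (camera adjusted p = 0.73). In somatosensory neurons 2 of 14 were lower (camera adjusted p = 0.014, adjusted p = 0.075 with an estimated correlation).

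Of 69 potassium channel genes, 8 rose and 16 fell from Tnnt1- to Calb2-anchored cells (camera adjusted p = 0.0055, adjusted p = 0.12 with an estimated correlation); of 68 tested between systems, 9 rose and 2 fell in motor neurons (camera adjusted p = 0.0035, adjusted p = 0.11 with an estimated correlation) and 4 rose and 15 fell in prefrontal neurons (camera adjusted p = 0.0034, adjusted p = 0.093 with an estimated correlation). Of 26 glutamate receptor genes, 3 rose and 8 fell in Calb2-anchored cells (camera adjusted p = 0.025, adjusted p = 0.12 with an estimated correlation). Of 11 burst and pacemaker channels, 2 rose and 4 fell in Calb2-anchored cells (camera adjusted p = 0.18), and 2 rose in motor neurons (camera adjusted p = 0.034, adjusted p = 0.21 with an estimated correlation). Of 14 synaptotagmins, which sense calcium for vesicle release, 2 rose in Necab1-anchored cells (camera adjusted p = 0.033, adjusted p = 0.092 with an estimated correlation) and 3 against Tnnt1-anchored cells alone (camera adjusted p = 0.025, adjusted p = 0.095 with an estimated correlation), while 4 rose, Syt5 among them (2.51 ± 0.25), and 3 fell between Calb2- and Tnnt1-anchored cells (camera adjusted p = 0.73).

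The other lists that passed camera with the preset correlation were as follows. In auditory neurons: axis anchors 1 higher and 0 lower of 3 (1 and 0 adjusted over the list alone, up, camera adjusted p = 0.0023, adjusted p = 0.059 with an estimated correlation). In motor neurons: axis anchors 0 higher and 1 lower of 3 (0 and 2 adjusted over the list alone, down, camera adjusted p = 0.012, adjusted p = 0.17 with an estimated correlation), respiratory chain 0 higher and 0 lower of 89 (0 and 0 adjusted over the list alone, up, camera adjusted p = 0.047, adjusted p = 0.64 with an estimated correlation). In somatosensory neurons: axis anchors 0 higher and 2 lower of 3 (0 and 2 adjusted over the list alone, down, camera adjusted p = 0.00058, adjusted p = 0.075 with an estimated correlation), oligodendrocyte 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone, up, camera adjusted p = 0.0072, adjusted p = 0.69 with an estimated correlation), ephrin 0 higher and 0 lower of 19 (1 and 2 adjusted over the list alone, down, camera adjusted p = 0.012, adjusted p = 0.10 with an estimated correlation). In visual neurons: axis anchors 0 higher and 0 lower of 3 (1 and 0 adjusted over the list alone, up, camera adjusted p = 0.041, adjusted p = 0.29 with an estimated correlation). In Calb2- against Tnnt1-anchored cells: matrix and core markers 1 higher and 2 lower of 4 (1 and 3 adjusted over the list alone, down, camera adjusted p = 0.0025, adjusted p = 0.057 with an estimated correlation), cortical glutamatergic neuron 0 higher and 1 lower of 4 (0 and 2 adjusted over the list alone, down, camera adjusted p = 0.043, adjusted p = 0.16 with an estimated correlation), respiratory chain 1 higher and 4 lower of 86 (0 and 3 adjusted over the list alone, down, camera adjusted p = 0.011, adjusted p = 0.70 with an estimated correlation). In Necab1-anchored cells against the others: heat shock genes 0 higher and 1 lower of 8 (0 and 3 adjusted over the list alone, down, camera adjusted p = 0.050, adjusted p = 0.20 with an estimated correlation), calcium channel 0 higher and 0 lower of 24 (0 and 0 adjusted over the list alone, up, camera adjusted p = 0.029, adjusted p = 0.18 with an estimated correlation), protocadherin 1 higher and 0 lower of 59 (1 and 0 adjusted over the list alone, up, camera adjusted p = 0.034, adjusted p = 0.38 with an estimated correlation), ribosomal protein 0 higher and 20 lower of 81 (0 and 32 adjusted over the list alone, down, camera adjusted p = 1.7e-18, adjusted p = 0.11 with an estimated correlation). In Necab1- against Tnnt1-anchored cells: matrix and core markers 1 higher and 3 lower of 4 (1 and 3 adjusted over the list alone, down, camera adjusted p = 0.014, adjusted p = 0.095 with an estimated correlation), midline and intralaminar markers 1 higher and 0 lower of 12 (5 and 0 adjusted over the list alone, up, camera adjusted p = 0.00062, adjusted p = 0.095 with an estimated correlation), modulatory receptors 3 higher and 0 lower of 28 (7 and 0 adjusted over the list alone, up, camera adjusted p = 0.014, adjusted p = 0.40 with an estimated correlation), oligodendrocyte 1 higher and 0 lower of 10 (1 and 0 adjusted over the list alone, up, camera adjusted p = 0.0040, adjusted p = 0.40 with an estimated correlation). Camera made no call in any contrast for astrocyte, endothelial and mural, microglia, oligodendrocyte precursor, habenula or reticular nucleus markers, nor for cadherins, semaphorins, sodium channels or mitochondrial transcripts; their lowest camera adjusted p was 0.15, 0.43, 0.32, 0.18, 0.19, 0.20, 0.25, 0.20, 0.15 and 0.10 in that order. Single members of these lists still passed in edgeR's test: over the contrasts, the higher and lower calls were 4 and 4 for astrocyte markers, 5 and 7 for reticular nucleus markers, 2 and 0 for habenula markers, 7 and 5 for cadherins, 14 and 11 for semaphorins, 17 and 17 for sodium channels and 1 and 2 for mitochondrial transcripts. Blood, ependymal and choroid, and GABA neuron markers had at most 1 expressed member, too few for a list test. The list median and the camera test had 1 sign and the list mean the other for potassium channels in motor neurons (median 0.24, mean -0.03) and in Calb2- against Tnnt1-anchored cells (median -0.10, mean 0.32), for burst and pacemaker channels in motor neurons (median 0.34, mean -0.24) and for glutamate receptors in Calb2- against Tnnt1-anchored cells (median -0.14, mean 0.14).

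The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes. It called 69 of 245 list and contrast pairs, 45 of which camera called too, with 1 direction in both tests, while 12 were called by camera only and 24 by fry only. Of the latter, 11 fell on lists without a camera call. In motor neurons these were astrocyte markers (up, fry adjusted p = 0.0011, though the median fold was -0.53; Slc1a2 and Aldoc rose among 5 tested), sodium channels (up, 0.034) and semaphorins (up, 0.039). In prefrontal neurons habenula markers were called (up, 0.036, 1 of 4 higher, Gpr151). From Tnnt1- to Calb2-anchored cells oligodendrocyte precursor markers (up, 0.017) and microglia markers (up, 0.038) were called with 0 of 3 members each passing in edgeR's test over all genes, and cadherins (up, 0.027). In Necab1-anchored cells against the others microglia markers were called (down, 0.038) and reticular nucleus markers (down, 0.0020), and against Tnnt1-anchored cells reticular nucleus markers (down, 0.0013) and sodium channels (up, 0.050). For oligodendrocyte markers fry made the call between Calb2- and Tnnt1-anchored cells (adjusted p = 0.011) but not in prefrontal (0.12) or somatosensory neurons (0.46) or between Necab1- and Tnnt1-anchored cells (0.098).

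Gad2, which encodes an enzyme that makes GABA, was the 1 GABA neuron marker tested, and it lay in few cells. UMIs of it were found in 16 of 388 prefrontal cells (400 UMIs) and 6 of 380 auditory cells (121 UMIs), while all motor, somatosensory and visual cells held 1, 2 and 4 UMIs. It averaged 7.74 ± 6.59 CPM in prefrontal sums (log2 fold 6.44 ± 0.93, adjusted p = 0.00011 in edgeR's test) and 4.80 ± 9.08 in auditory sums (log2 fold 3.07 ± 0.92, adjusted p = 0.044), and was lower in motor sums (adjusted p = 0.031). It was also higher in Calb2-anchored cells (478 UMIs in 18 of 611 cells) than in Tnnt1-anchored cells (2 UMIs; adjusted p = 0.039). No motor, somatosensory or visual sum held more than 2 UMIs, so the fitted folds rest on counts near 0. For Gad2, Prefrontal replicate 2 held 233 and replicate 3 118 of the 400 prefrontal UMIs, and the prefrontal call ended without replicate 3 (log2 fold 4.08) but not without replicate 2 (5.85). The auditory call ended without any 1 of auditory replicates 1 and 5 (2.73 and 0.68), motor 2 to 5, prefrontal 1 to 4, somatosensory 2 and 3, visual 1 and 2 and batches 1 and 3 (3.34 and 0.61), with cells summed per sort date and with 1 dispersion for all genes. The motor call ended without any 1 of motor replicates 2 to 5, prefrontal 2, somatosensory 1 and 2 and batches 1 and 3, without cells showing another type, per sort date, with 1 dispersion and with no batch term. The Calb2 call ended without any 1 of auditory replicates 1 and 5, prefrontal 1 to 3 and batches 1 to 3, with DESeq2 and with the minimum of cells doubled.

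Of 10 oligodendrocyte genes, 3 were higher in Calb2- than in Tnnt1-anchored cells, and the list median was 2.87 (camera adjusted p = 0.00031, adjusted p = 0.28 with an estimated correlation), though in the stricter anchor classes the median was -7.87 with all 10 below 0. Depth alone is argued against: thinning to 20000 UMIs cut the median to 1.58, above the bound set beforehand, with 2 genes passing. Calb2-anchored cells were not deeper (median 87726 UMIs against 90468). Of the list's UMIs in Calb2-anchored cells, 82.4% lay in 31 of 611 cells, as did 72.2% in 38 of 756 Tnnt1- and 88.1% in 27 of 532 Necab1-anchored cells, so this share alone does not set the classes apart. The 20 cells with the authors' flag held 1854 CPM of Mbp and 1129 of Mobp beside 413 of the neuronal Slc17a6, against 18.2, 0.840 and 709 in the other 1952. Without them the list stood at 70.4 CPM in Calb2-, 65.9 in Necab1- and 42.6 in Tnnt1-anchored cells, against 252, 307 and 87.8 with them. Without those cells the Calb2 minus Tnnt1 median was 0.39 and 0 of 5 tested genes passed in edgeR's test (1 at an unadjusted p under 0.05; DESeq2, not run without those cells, called 3 of 10), while the Necab1 minus Tnnt1 median went from 1.54 to 0.74 and the somatosensory one from 1.60 to -0.53. A small number of cells that carry oligodendrocyte RNA is therefore a candidate explanation, although hand sorting of labelled neurons would remove oligodendrocytes themselves; no biological explanation was tested.

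One prefrontal cluster, the authors' number 3, held 52 of 64 and 61 of 74 cells in prefrontal replicates 1 and 2, and 0 of 170 and 0 of 80 cells in replicates 3 and 4, which allows shares of up to 1.76% and 3.75%. The relay genes Slc17a6 and Tcf7l2 were near their level in the animals' other 12 and 13 prefrontal cells (lowest log2 ratio -0.47). These 2 genes alone cannot exclude cells from outside the thalamus. Replicates 1 and 2 are those of batch 1. Between them and the later prefrontal sums, 100 genes differed by at least 2 on the log2 scale (median 2.34). Between batch 1 and later sums 94% of these genes differed in the same direction in auditory (median 2.16) and 91% in motor neurons (median 2.05, 87.7% of the prefrontal one). Sequencing batch may thus contribute, but these genes came from whole sums and not from the cluster. Batch alone is argued against. In replicates 1 and 2, 12 and 13 cells lay in the other prefrontal clusters, which the later animals hold too. The authors' cluster 9 over all systems held 99 prefrontal and 0 auditory or motor cells, although batch 1 held all 3 systems. A different site of labelling in these animals stays open and was not tested.

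Other splits of the same sums were counted to ask whether chance can be excluded. Of 100 splits of the 21 sums, 1 gave as many genes as the real one among systems (2173, highest other 5), 1 for auditory (1371, highest other 134), 1 for motor (673, highest other 11) and 1 for prefrontal neurons (1578, highest other 96), so chance can be excluded for these counts, if sums are taken as exchangeable. For somatosensory neurons 2 of 100 gave as many (40, highest other 84) and for visual neurons 3 of 100 (25, highest other 132). The larger splits here placed 3 of the 4 prefrontal sums together, which points to the structure of the samples. Of the 21 sums, 14 shared a sort date with another sum of the same system, so they are not fully exchangeable. With cells summed per sort date (14 sums), 1 of 100 splits gave as many genes among systems (1317, highest other 41), 1 of 100 for auditory (1004, highest other 6), 1 of 100 for motor (156, highest other 26) and 1 of 100 for prefrontal neurons (1219, highest other 108), so chance can be excluded for these counts between dates. For visual neurons 3 of 100 did (17, highest other 277), and the highest, several times the real count, placed 2 of the 3 prefrontal dates together, which again points to the structure of the samples. Somatosensory neurons had 2 dates and 6 genes, and 3 of 100 splits gave as many (highest other 30). Whether the somatosensory and visual counts exceed what such structure gives stays open. Exchanging the classes within animals gave as many genes in 1 of 24 exchanges for Calb2 minus Tnnt1 (1600, highest other 0). The same held for Necab1 against the others (746, highest other 1) and Necab1 minus Tnnt1 (638, highest other 1). Anchor classes, like the authors' clusters, were made from the same counts, so splits of neither decide about chance. Those of the clusters follow as values. As many genes were found in 1 of 25 over all systems (4914, highest other 1856, median 478), 1 of 25 in auditory (812, highest other 376), 1 of 25 in motor (1075, highest other 84), 1 of 24 in somatosensory (718, highest other 68), 1 of 25 in visual (296, highest other 115) and 2 of 12 in prefrontal neurons (574, highest other 574). Within systems the exchanges between Calb2- and Tnnt1-anchored cells were too few for a share under 0.05: 1 of 16 in auditory (281, highest other 0), 4 of 16 in motor (1, highest other 1), 1 of 4 in prefrontal (312, highest other 0) and 1 of 8 in visual neurons (80, highest other 3).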
